A study of Homo sapiens with 2 samples.

How the data were processed

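Human cord blood cells carrying CD34 were profiled as 2 droplet single-cell libraries made with the 3' chemistry of the 10x Chromium system, 1 from uncultured cells and 1 from cells cultured for 2 days with cytokines and valproic acid. Per the labels' protocols, cells were enriched with magnetic beads and sorted by flow cytometry, and the stated cell numbers, about 1528 and 4921, equal the numbers of barcodes in the matrices. The deposited values are raw counts of unique molecular identifiers (UMIs) per gene and cell, which the authors made with Cell Ranger 1.3.1 against hg19, per the submitters' processing notes. No annotation of cells and no map of cells to donors was used. The matrices list 32738 genes, and genes are named here by the symbols that the files pair with Ensembl identifiers, 95 symbols occurring more than once. The reference annotation at hand is on another genome build, so no coordinates are given.

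A barcode was kept as a cell with at least 200 detected genes and at most 20% of its UMIs from mitochondrially encoded genes. At day 0 this left out 16 barcodes (15 under 200 genes and 2 over 20%, 1 of them both), and at day 2 it left out 3. The quartiles of UMIs per kept cell were 1134 and 1970 at day 0 and 3678 and 6716 at day 2, so a UMI share or level from the day 2 library has the smaller counting error. Scrublet, run through scanpy, called 0 doublets in either library among 6430 cells, which means that it has not worked, so no doublets were removed and cells of very high UMI counts were instead left out in an alternative.

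UMIs were summed over kept cells for each gene and library and scaled to the library total as CPM. With 1 library per group there was no test, and no p-value or standard error was made from cells. Each CPM has an exact 95% Poisson interval, each ratio an exact conditional binomial (Clopper-Pearson) interval and each share of cells a Clopper-Pearson interval, all covering counting error only and not the variation between donors or cultures. Sums under 3 UMIs were set to 3 for ranking and for list medians, and this floor corresponds to 1.2 CPM at day 0 and 0.113 CPM at day 2. A gene at 0 UMIs in 1 library has a ratio against that floor, printed as a lower bound, and a gene with 1 to 3 UMIs has the plain ratio with its counting interval. The 2-sided 95% intervals reach further than this floor. For 0 UMIs at day 0 the upper limit is 1.47 CPM, and the ratio of HBG1 has a lower limit of 1149 against 1413 from the floor. No ratio is given where both sums were at or under the floor.

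The 30 pathway lists and 10 cell type marker lists were fixed before the data were examined, as were the cell filter, the size rule of at least 2-fold, most alternative settings and the rule for named genes. Of their 1002 distinct symbols, 986 were found in the files, 4 more were matched through their identifier and 12 had no match. A list is described by the median log2 ratio of its members at 10 CPM or more in at least 1 library, an exact order-statistic interval over members, the numbers at least 2-fold higher and lower, and the percentile of its median among 10000 random lists of the same size drawn within 20 bins of mean expression (seed 1). Several lists share genes, such as BTG2 (p53 and immediate early) and GATA2 (stem, and basophil, eosinophil and mast cell).

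Named genes were the 15 highest and 15 lowest ratios among genes at 50 CPM or more in at least 1 library, the 2 highest and 2 lowest members of each list at 20 CPM or more, of which a part is printed, and a fixed set of stem, p53, cycle and metabolic genes. A few genes that this rule chose are not reported here, though they stay in the list counts. Clone-style names, X-inactivation RNAs, Y-linked genes, immunoglobulin and T cell receptor segments and genes set by common germline deletions or haplotypes were left out of the first part. TOP2A was printed outside this rule, from the mitotic list, for its share of cells, and AHRR, TIPARP, PHGDH, MTHFD2, SHMT2, PSPH, FOS, JUN, NFKBIA and DUSP1, in the closing part, were chosen after their values were seen.

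Shares of cells with a UMI of a gene were compared after each cell was thinned at random without replacement to 1000 UMIs. Cells were clustered within each library with scanpy 1.11.5, from counts scaled to 10000 per cell, logarithms, 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.8. A cluster was named after a cell type only with at least 3 markers of that type among its 20 leading genes found in at least 10% of its cells and no type with more. This naming rule was set after the data were seen. Class shares are not compared between libraries.

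After seeing that single day 0 cells held much of the count of some genes, all values were also computed from capped counts. In these, for each gene, the 1 in 300 cells with the most UMIs were set to the next highest count. A gene found in no more cells than that had each count set to 1, which can make its capped fold larger than the deposited one. The cap removed 6.07% of day 0 UMIs and 0.626% of day 2 UMIs. The alternative settings chosen before the data were examined were every barcode, 500 detected genes, 10% mitochondrial UMIs, the top 5% of cells by UMIs left out, TMM factors (edgeR 4.0.16 in R 4.3.3), a median-of-ratios factor, scaling to UMIs outside ribosomal protein and mitochondrially encoded genes, the mean of per-cell CPM, UMIs per cell, thinned cells, thresholds of 5 and 50 CPM, pseudocounts of 1 and 10 CPM, other thinning depths and other clusterings.

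Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The ratios and percentiles were tested on simulated data with known changes, drawn for the day 2 over day 0 comparison from the real means and depths over 6774 genes. Of genes raised 3-fold or 6-fold, 100% were past 2-fold, as were 98% of those lowered 3-fold and 100% of those lowered 6-fold. Of unchanged genes 0.0456% were past 2-fold, and 94.8% of their intervals held the true ratio. For genes raised 3-fold and 6-fold, 98% and 92% of intervals held it, and for genes lowered 3-fold and 6-fold, 90% and 97.8%. The simulated sums had Poisson counting error only, as the intervals assume, and no counts held by single cells. The coverage therefore does not extend to the 371 of 1866 day 0 genes with over 25% of their UMIs in 1 cell. Of 200 unchanged lists, 3% fell outside the central 95% of their random lists.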

Results

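The series held 2 single-cell RNA libraries of human cord blood cells carrying CD34, the surface glycoprotein used to enrich haematopoietic stem and progenitor cells. The day 0 library came from cells that had not been cultured. The day 2 library came from cells kept for 2 days in serum-free medium with thrombopoietin at 100 ng/ml, FLT3 ligand at 100 ng/ml, interleukin 3 at 50 ng/ml, stem cell factor at 150 ng/ml and valproic acid, an inhibitor of histone deacetylases, at 1 mM. Each group had 1 library, so no difference had a replicate check and no test was possible. The labels do not state whether both libraries came from the same donor. Valproic acid, cytokines and time in culture differed together, and a difference of donor or sort could add to them. The day 0 file held 1528 barcodes, of which 1512 were kept as cells with 2501214 UMIs, and the day 2 file held 4921 barcodes, of which 4918 were kept with 26661808 UMIs. The median cell held 1497.5 UMIs and 514 detected genes at day 0 and 4992 UMIs and 1751 genes at day 2, a 3.33-fold higher median UMI count. At a common depth of 1000 UMIs, reached by 1232 day 0 cells (280 left out) and all 4918 day 2 cells, the median number of detected genes was 402 at day 0 and 564.5 at day 2.

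The comparison of the libraries bears on the question named in the series title, whether stem cells that expand in culture alter their mitochondria and engage the p53 pathway. Gene sums were compared as counts scaled to the library total (CPM), and a gene counted as measured with 10 CPM or more in at least 1 library. The median of the 7447 measured genes was 0.59 higher on the log2 scale in the day 2 library. Of these genes, 2645 were at least 2-fold higher and 899 at least 2-fold lower, so counts within lists are read against those shares. Each gene list is therefore set beside the median of random lists of matched expression, and percentiles among 10000 such lists are given as a description of these libraries. Brackets after a fold or CPM hold 95% intervals that cover counting error only, and those after a list's median are 95% intervals over its genes. Capped values are given because single day 0 cells held much of some genes. In them, a gene's 6 highest cells at day 0 and 17 highest at day 2 were lowered to the next highest cell. A gene found in no more cells than these was set to 1 UMI in each, which can raise a capped fold.

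Genes of mitosis and DNA replication were higher in the day 2 library. Of 52 measured G2 and M phase genes, 47 were at least 2-fold higher in the day 2 library and 0 were at least 2-fold lower, with a median log2 ratio of 3.43 [2.90, 3.83] against 0.76 for matched random lists. CDK1, the kinase that drives entry into mitosis, stood at 1.60 CPM [0.436, 4.09] at day 0 and 171 CPM [166, 176] at day 2, a 107-fold higher level [41.7, 392]. MKI67, which encodes the proliferation antigen Ki-67, was 33.1-fold higher [12.9, 122], and CDCA3, a mitotic regulator, had 3 UMIs at day 0 and a ratio of 40.9 [14.0, 198]. CKS2, which binds cyclin-dependent kinases, was 1.2-fold higher [1.11, 1.29]. Of 38 measured S phase genes, 28 were at least 2-fold higher and 0 lower, with a median of 1.83 [1.10, 2.32] against 0.62. RRM2, a subunit of ribonucleotide reductase, was 23.5-fold higher [14.7, 40.4]. PCNA, the sliding clamp of DNA polymerase, was 3.90-fold higher [3.23, 4.74], whereas CDCA7 was 1.47-fold lower at day 2. Both lists stood at percentile 100 of their random lists.

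Regulators of the G1 phase were mixed, with 5 of 14 at least 2-fold higher, 3 lower and a median of 0.63 [-1.35, 3.04] against 0.67. CCNE1, which encodes cyclin E1 and acts at the G1 to S transition, was 10.0-fold higher [4.83, 25]. CDK6, a partner of D-type cyclins, was 4.53-fold lower in the day 2 library [4.12, 4.98], and RB1, the retinoblastoma protein gene, was 3.98-fold lower. CDKN1C, the gene of the CDK inhibitor p57, stood at 4.80 and 8.29 CPM, and the interval of its ratio included 1 (1.73-fold [0.969, 3.39]). At the common depth, a UMI of TOP2A, the mitotic topoisomerase, was found in 0.568% of day 0 cells [0.229, 1.17] and 15.2% of day 2 cells [14.2, 16.3]. These shares were 0.269% and 8.60% at 500 UMIs, 3.55% and 28.5% at 2000 UMIs, which only 366 day 0 cells reached, and 1.32% and 49.4% without thinning.

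Stem and primitive progenitor genes were lower in CPM in the day 2 library. Of 34 measured genes, 18 were at least 2-fold lower and 3 at least 2-fold higher, with a median of -1.09 [-1.80, -0.04] against 0.56 and percentile 0 of the random lists. Counted as UMIs per cell without scaling, the split turned to 4 lower and 16 higher, as the day 2 cells held more UMIs. AVP, a transcript abundant in uncultured primitive cells, stood at 424 CPM [399, 450] at day 0 and 39.6 CPM [37.3, 42.1] at day 2, a 10.7-fold lower level [9.81, 11.7]. CD34 was 2.07-fold lower [1.86, 2.29], from 178 to 85.8 CPM, and 1.65-fold lower with capped counts. SPINK2, a protease inhibitor gene, was 2.60-fold lower [2.49, 2.72]. PROM1, which encodes the surface protein CD133, was 4.39-fold lower, and MLLT3, a regulator of stem cell maintenance, was 3.36-fold lower. HLF, a transcription factor of primitive cells, was 16.4-fold lower, but 111 of its 132 day 0 UMIs lay in 1 cell, and the capped fold was 2.85 [1.68, 4.65]. In stem-like clusters found with capped counts (317 and 761 cells), which these genes helped to define, the list's median was -0.30, with CD34 at a log2 ratio of 0.12.

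Other genes of the same list ran the opposite way. GATA2, a transcription factor of stem cells and of the mast cell lineage, was 4.73-fold higher [4.09, 5.49] in the day 2 library, at 75.2 and 355 CPM, but had a log2 ratio of -0.91 within the stem-like clusters of capped counts. PROCR, the protein C receptor used to mark cultured stem cells, was 6.81-fold higher [3.43, 15.9]. THY1, the surface protein CD90, had 2 UMIs at day 0 and a ratio of 23.8 [6.55, 197]. KIT, the stem cell factor receptor, stood at 12 and 13.7 CPM with an interval of the ratio that included 1 [0.788, 1.72]. CD38, a surface protein gained on commitment, was lower in the day 2 library, at 20.4 and 2.18 CPM (9.37-fold [6.31, 13.9]). Of 12 pluripotency-associated genes, only DPPA4 was measured, at 28.0 CPM at day 0 and 25.1 CPM at day 2.

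The day 2 library split into 8 clusters, 4 of which carried enough fixed markers for a name. These were a stem and primitive progenitor-like cluster of 633 cells (markers AVP, CRHBP and HOPX), an erythroid-like cluster of 567 cells (globins, ALAS2 and CA1), a basophil, eosinophil and mast cell-like cluster of 793 cells (HDC, MS4A3 and CPA3, led by FST and RNASE2) and a granulocyte and monocyte progenitor-like cluster of 244 cells (MPO, LYZ, PLAC8 and RNASE2). An unnamed cluster of 311 cells was led by mitotic genes such as KIF20A and CENPA, and the others by MZB1 (1317 cells), PRSS23 (889 cells) and IGFBP5 (164 cells). Of 7 day 0 clusters, only 1 of 31 cells was named, as monocyte and conventional dendritic cell-like (S100A8, S100A9, MS4A6A, FCN1 and CD14). The other day 0 clusters were led by IGJ (266 cells), TTC14 (400), UBE2N (336), TPSAB1 (398), ACY3 (62) and FAM110D and MGP (19).

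At 1000 UMIs per cell, a UMI of AVP was found in 24.8% of day 0 cells [22.4, 27.3] and 4.25% of day 2 cells [3.70, 4.85], against 27.6% and 15.1% without thinning. The AVP shares were 14.9% and 2.44% at 500 UMIs, and 14.8% [11.3, 18.8] and 7.63% [6.89, 8.42] at 2000 UMIs, so the size of this difference depended on depth and on the cells that reached it. For SPINK2 the shares were 53.6% [50.7, 56.4] and 31.9% [30.6, 33.3], against 64.8% and 62.4% without thinning. Those of CD34 were 12.1% [10.3, 14.0] and 9.19% [8.40, 10.0], and the unthinned shares of 17.0% and 33.9% ran against the CPM. At 2000 UMIs the CD34 shares, 19.4% [15.5, 23.8] and 16.6% [15.6, 17.7], had overlapping intervals. In the erythroid-like cluster of the day 2 library, which should lack AVP and SPINK2, the thinned shares were 0.882% for AVP, 2.47% for SPINK2 and 3.70% for CD34. The share of CD34 is not a background level. CD34 stood at 37.6 CPM there, against 27.0 CPM in the granulocyte and monocyte progenitor-like and 49.1 CPM in the basophil, eosinophil and mast cell-like cluster. Apart from the depths named, cells in these thinned comparisons had 1000 UMIs, from unthinned medians of 1497.5 at day 0, 4992 at day 2 and 7646 in the erythroid-like cluster.

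**Figure D1:**
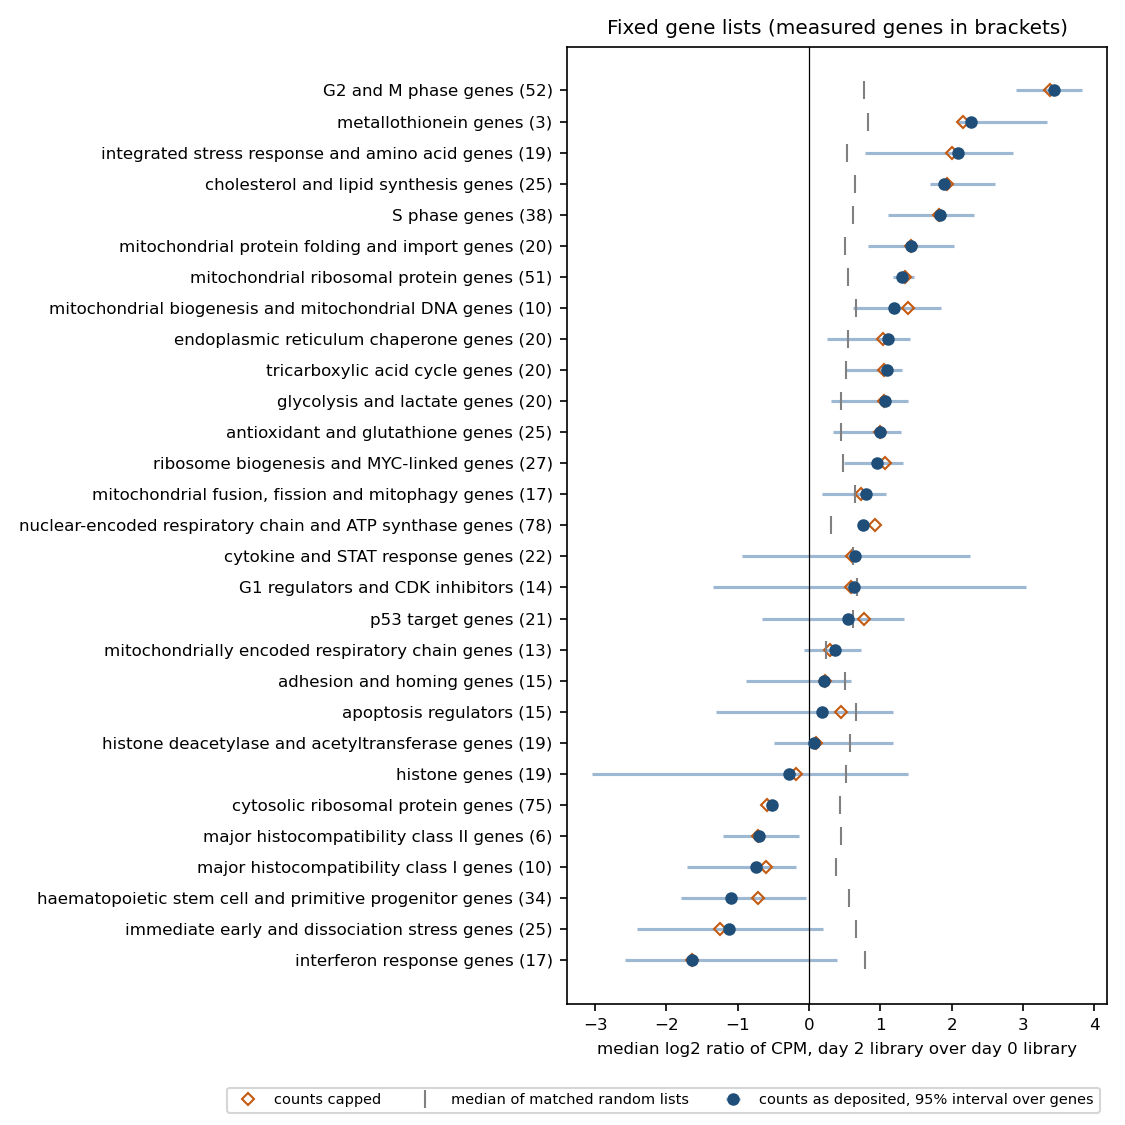
Median log2 ratio of CPM of each pathway list with at least 3 measured genes, day 2 library over day 0 library. Filled points are counts as deposited with 95% intervals over genes (75% for the 3 metallothionein genes), diamonds are capped counts and ticks are medians of matched random lists. G2 and M phase genes lie highest at 3.43, interferon response genes lowest at -1.63 and p53 targets, at 0.55, beside their random lists at 0.61. Counted per cell without scaling, the stem, class I, class II and cytosolic ribosomal protein lists lay above 0.

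The p53 target genes did not stand apart from random lists as a group. Of 21 measured targets, 7 were at least 2-fold higher in the day 2 library and 5 at least 2-fold lower, with a median of 0.55 [-0.66, 1.33] against 0.61 and percentile 40.4 of the random lists. The split was 5 higher and 6 lower with a median-of-ratios scaling, and 16 higher and 1 lower per cell without scaling. With capped counts it was 7 higher and 3 lower of 19, with a median of 0.77 [0.07, 1.49] against 0.74 and percentile 55.05, and 10 higher and 4 lower in the stem-like clusters. CDKN1A, which encodes the CDK inhibitor p21, stood at 7.60 CPM [4.57, 11.9] at day 0 and 36.1 CPM [33.8, 38.4] at day 2. This was 4.75-fold higher [3.02, 7.92] over whole libraries. Among day 2 clusters CDKN1A ranged from 10.2 to 80.6 CPM, highest in the erythroid-like cluster, and was 13.9 CPM in the stem-like one. FDXR, the mitochondrial ferredoxin reductase, was 5.48-fold higher [3.04, 11]. In contrast, GADD45A, a growth arrest gene, was 2.92-fold lower [2.52, 3.37] in the day 2 library and BTG2, an antiproliferative gene that the immediate early list also holds, was 5.33-fold lower. TNFRSF10B, a death receptor for TRAIL, was 9.83-fold lower with 61 of its 71 day 0 UMIs in 1 cell, and the capped fold of 1.39 had an interval that included 1. MDM2, a ubiquitin ligase and target of the pathway, stood at 5.20 and 4.69 CPM, with an interval of the ratio that included 1, at 0.902 [0.509, 1.74]. Protein level and pathway activity were not measured.

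Apoptosis regulators were mixed as well, with 5 of 15 at least 2-fold higher, 4 lower and a median of 0.18 [-1.30, 1.18] against 0.66, and 3 higher and 5 lower with TMM. BCL2L1, which encodes the survival protein BCL-XL, was 4.15-fold higher [2.92, 6.08]. PMAIP1, the gene of the BH3-only protein NOXA, was 4.97-fold lower in the day 2 library and belongs to the p53 list too.

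Nuclear genes of the respiratory chain were higher in CPM in the day 2 library. Of 78 measured genes, 20 (34 with capped counts) were at least 2-fold higher and 0 at least 2-fold lower, with a median of 0.76 [0.69, 0.85] against 0.31 and percentile 99.99. The share at least 2-fold higher was below that of all measured genes, 2645 of 7447. With capped counts it was above that of all genes, 2770 of 7286. NDUFB3, a complex I subunit, was 5.30-fold higher [4.63, 6.11], from 84.0 to 445 CPM. NDUFV3, another complex I subunit, was 4.30-fold higher [3.24, 5.83], whereas ATP5G2, a subunit of ATP synthase, was 1.34-fold lower in the day 2 library. The 13 genes encoded in mitochondrial DNA had a median of 0.37 [-0.07, 0.73] against 0.23, with 2 at least 2-fold higher and percentile 63.2. MT-ND6 was 3.53-fold higher [2.84, 4.45] and MT-ND5 2.40-fold higher [2.28, 2.54], both complex I subunits, while MT-ND4L was 1.36-fold lower. Mitochondrially encoded genes took 3.79% of UMIs at day 0 [3.77, 3.82] and 5.26% at day 2 [5.26, 5.27]. With a median-of-ratios scaling the median of this list was -0.05.

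Mitochondrial ribosomal protein and import genes were higher in the day 2 library as well. Of 51 measured mitochondrial ribosomal protein genes, 41 were at least 2-fold higher in the day 2 library and 0 lower, with a median of 1.3 [1.18, 1.47] against 0.55. MRPL17 was 17.3-fold higher [10.1, 32.6] and MRPL41 7.15-fold higher [6.08, 8.47], both subunits of the large mitochondrial ribosome. MRPL22, with 137 of 386 day 0 UMIs in 1 cell, was 1.07-fold higher as deposited and 2.89-fold higher capped. Among 20 genes of mitochondrial protein folding and import, 13 were at least 2-fold higher and 0 lower, with a median of 1.44 [0.82, 2.03] against 0.50. TIMM10, a chaperone of the intermembrane space, was 7.10-fold higher [5.75, 8.86] and GRPEL1, a partner of mitochondrial HSP70, was 6.48-fold higher [4.27, 10.4]. Among 10 biogenesis and mitochondrial DNA genes, 6 were at least 2-fold higher, with a median of 1.18 [0.61, 1.84] against 0.65 and percentile 91.4, inside the range of their random lists. TFAM, which packages mitochondrial DNA, was 3.14-fold higher [2.39, 4.21], at 21.2 and 66.5 CPM. PPARGC1A, the coactivator PGC-1 alpha, had 0 UMIs in both libraries, which allows up to 1.2 CPM at day 0 and 0.113 CPM at day 2. Fusion, fission and mitophagy genes had a median of 0.80 [0.18, 1.08] against 0.64, with 7 of 17 at least 2-fold higher, 0 lower and percentile 70.9.

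Glycolysis and tricarboxylic acid cycle genes were also higher. Of 20 measured glycolysis and lactate genes, 11 were at least 2-fold higher and 0 lower, with a median of 1.06 [0.31, 1.39] against 0.45 and percentile 99.75. SLC16A3, a lactate exporter, was 17.5-fold higher [10.9, 30], and ENO2, an enolase, 9.62-fold higher [4.65, 24.0]. LDHA, the lactate dehydrogenase subunit, was 1.24-fold higher [1.18, 1.31] at 649 and 807 CPM. SLC2A1, the glucose transporter GLUT1, was 1.95-fold higher [1.16, 3.52] at 6.0 and 11.7 CPM. Of 20 tricarboxylic acid cycle genes, 11 were at least 2-fold higher and 0 lower, with a median of 1.09 [0.52, 1.3] against 0.52 and percentile 98.8, which was 94.7 with capped counts and so inside the random lists. IDH1, the cytosolic isocitrate dehydrogenase, was 6.29-fold higher [4.10, 10.2]. PDHB, a pyruvate dehydrogenase subunit, was 1.35-fold lower as deposited and 1.44-fold higher with capped counts.

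Antioxidant and glutathione genes had a median of 0.99 [0.33, 1.29] against 0.45, with 12 of 25 at least 2-fold higher and 1 lower (6 and 3 with a median-of-ratios scaling). GCLM, a subunit of the enzyme that limits glutathione synthesis, was 10.9-fold higher [6.09, 22.0]. NQO1, a quinone reductase, was 6.12-fold higher [3.94, 10.0]. SOD2, the mitochondrial superoxide dismutase, was 1.75-fold lower in the day 2 library, and TXNIP, an inhibitor of thioredoxin, was 7.01-fold lower, or 4.17-fold lower with capped counts. All 3 measured metallothionein genes, which bind metal ions, were at least 2-fold higher, with a median of 2.27. MT1X was 10.1-fold higher [6.32, 17.4] and MT2A 4.24-fold higher [3.66, 4.93].

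**Figure D2:**
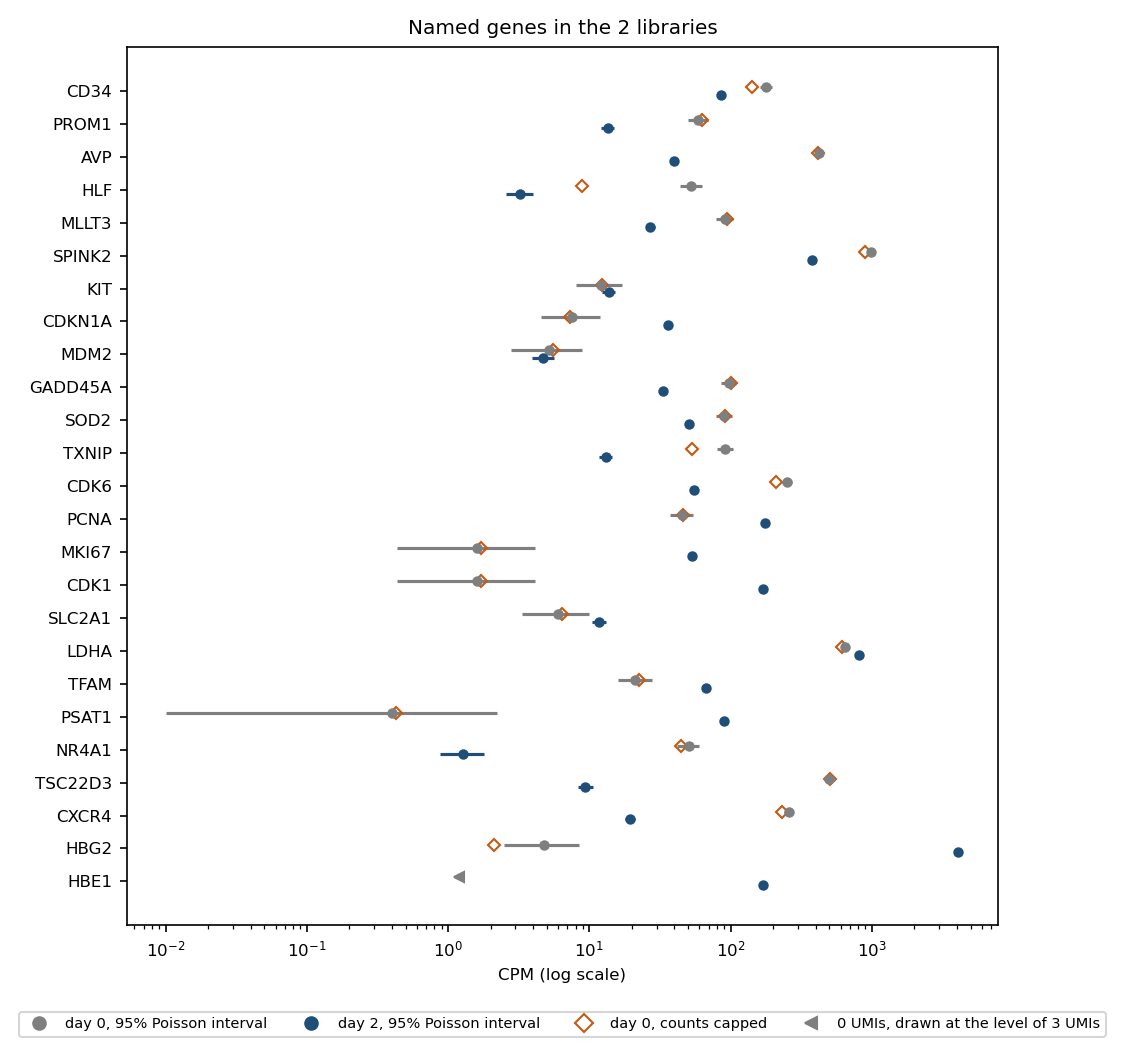
CPM of 25 named genes in the day 0 library (grey) and the day 2 library (blue) on a log scale, with 95% Poisson intervals, and day 0 levels from capped counts (diamonds). AVP and CXCR4 lie lower in the day 2 library, CDKN1A, CDK1 and HBG2 higher, and MDM2 and KIT at overlapping levels. The capped level of HLF lies below its deposited day 0 level.

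Immediate early genes, which respond to handling and signalling within minutes, were on balance lower in the day 2 library. Of 25 measured genes, 13 were at least 2-fold lower and 6 higher, with a median of -1.12 [-2.41, 0.20] against 0.66 and percentile 0. Per cell without scaling, 6 were lower and 12 higher. NR4A2 was 80.7-fold lower and NR4A1 39.5-fold lower, both orphan nuclear receptors. EGR1, a growth factor response gene, was 8.22-fold higher [3.96, 20.5]. CXCR4, the receptor that retains stem cells in bone marrow, was 13.2-fold lower [11.8, 14.9] at 257 and 19.5 CPM. The adhesion and homing list as a whole had a median of 0.21 [-0.89, 0.59] against 0.50, with 3 of 15 at least 2-fold higher and 3 lower, and 2 and 4 with TMM. LGALS1, which encodes galectin 1, was 9.43-fold higher [8.72, 10.2] and CD9, a tetraspanin, 14.6-fold higher [9.44, 24.0].

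Amino acid, protein folding and lipid genes were higher in the day 2 library. Of 19 integrated stress response and amino acid genes, 13 were at least 2-fold higher and 2 lower, with a median of 2.09 [0.78, 2.85] against 0.54. The higher genes included ASNS, asparagine synthetase, at 11.1-fold [5.80, 24.3]. The lower ones were DDIT3, the transcription factor CHOP, at 6.73-fold and DDIT4, an inhibitor of mTORC1, at 2.96-fold. Of 20 endoplasmic reticulum chaperone genes, 11 were at least 2-fold higher and 0 lower, with a median of 1.11 [0.25, 1.42] against 0.55 and percentile 99.4 (96.5 with capped counts, inside the random lists), and CRELD2 was 8.47-fold higher [6.08, 12.2]. Of 25 cholesterol and lipid synthesis genes, 21 were at least 2-fold higher and 1 lower, with a median of 1.89 [1.69, 2.60] against 0.64. SQLE, squalene epoxidase, was 10.1-fold higher [7.35, 14.3]. Ribosome biogenesis genes had a median of 0.95 [0.49, 1.31] against 0.47, with 13 of 27 at least 2-fold higher and 0 lower, and MYC, a driver of that programme, was 4.85-fold higher [4.12, 5.73]. Cytosolic ribosomal protein genes instead had a median of -0.52 [-0.61, -0.47] against 0.43, with 5 of 75 at least 2-fold lower and 0 higher, and took 43.2% of UMIs at day 0 and 29.1% at day 2. Per cell without scaling, 53 of them were at least 2-fold higher and 0 lower. RPL17 was 4.43-fold lower, a value that is uncertain because it shares sequence with pseudogenes and a readthrough gene.

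Cytokine response and chromatin genes were mixed. Of 22 cytokine and STAT response genes, 9 were at least 2-fold higher and 5 lower, with a median of 0.64 [-0.94, 2.26] against 0.62, and 8 and 7 with a median-of-ratios scaling. SOCS1, a feedback inhibitor of JAK kinases, had 3 UMIs at day 0 and a ratio of 29.3 [10.0, 142], whereas PIM2, a survival kinase, was 4.22-fold lower. Of 19 histone deacetylase and acetyltransferase genes, 6 were at least 2-fold higher and 4 lower (2 and 4 with a median-of-ratios scaling), with a median of 0.07 [-0.50, 1.17] against 0.57. HDAC9 was 6.78-fold lower and HDAC8 3.84-fold higher [2.38, 6.62]. Of 19 histone genes, 6 were at least 2-fold higher and 8 lower (4 and 8 with a median-of-ratios scaling), with a median of -0.28 [-3.05, 1.38] against 0.52. HIST1H4C, a replication-linked H4 gene, was 11.2-fold higher [10.0, 12.6] and HIST2H2BE, a gene whose transcript can be polyadenylated, 58.0-fold lower. H1F0, a linker histone gene known to respond to deacetylase inhibitors, stood at 92.4 and 104 CPM, a ratio of 1.12 [0.981, 1.29] that was 1.46 with capped counts.

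Interferon and antigen presentation genes were lower in CPM in the day 2 library. Of 17 interferon response genes, 9 were at least 2-fold lower and 1 higher, with a median of -1.63 [-2.58, 0.38] against 0.79, and 4 were lower and 7 higher per cell without scaling. IRF1, an interferon-induced transcription factor, was 7.39-fold lower, and the higher gene was RSAD2, an antiviral enzyme gene, at 9.05-fold [4.13, 24.8]. Of 10 class I genes, 2 were at least 2-fold lower and 0 higher, with a median of -0.75 [-1.71, -0.18] against 0.38. Of 6 class II genes, 1 was at least 2-fold lower and 0 higher, with a median of -0.71 [-1.20, -0.14] against 0.45. With TMM and median-of-ratios scaling, 5 and 6 class I genes and 3 and 3 class II genes were at least 2-fold lower. The class II gene lower in CPM was HLA-DRA, the class II alpha chain, which stood at 1281 and 557 CPM, 2.30-fold lower [2.21, 2.39]. Per cell without scaling, 5 class I and 3 class II genes were at least 2-fold higher and 0 lower. In the stem-like clusters of capped counts, 2 class I genes were higher and 2 lower, and 1 class II gene was higher and 0 lower.

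The 15 genes with the highest ratios among those at 50 CPM or more were led by globins, the oxygen carriers of red cells. HBG1, at 0 UMIs at day 0, was at least 1413-fold higher, and HBG2 was 853-fold higher [488, 1651]. With capped counts HBG2 was 1869-fold higher [801, 5756], as the cap set its 12 day 0 UMIs, in 5 cells, to 1 UMI per cell. HBA1 and HBA2 had 2 UMIs each at day 0 and ratios of 658 [182, 5437] and 388 [107, 3201], and HBE1, with 0 UMIs at day 0, was at least 142-fold higher, or at least 83.9-fold capped. HBG1 and HBG2, and likewise HBA1 and HBA2, are near-identical, so the split within each pair is uncertain. Summed globin was 263-fold higher among kept cells and 17.3-fold higher with every barcode, as 2 day 0 barcodes under 200 detected genes were rich in globin. CYP1B1 and CYP1A1, cytochrome P450 enzymes induced through the aryl hydrocarbon receptor, had 0 UMIs at day 0 and were at least 354-fold and 58.6-fold higher. CBS, cystathionine beta-synthase, was at least 60.6-fold higher and TNNT1, a troponin, at least 56.8-fold higher, both from 0 UMIs at day 0. PSAT1, an enzyme of serine synthesis, IGFBP4, which binds insulin-like growth factors, and HES6, a transcriptional regulator, each had 1 UMI at day 0, with ratios of 223 [40.1, 8830], 231 [41.4, 9115] and 158 [28.3, 6232]. LAT, a signalling adaptor, was 104-fold higher [47.9, 284], and CCL2, a chemokine, 58.0-fold higher [24.8, 179]. CDK1 was the remaining gene.

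Of the 15 genes with the lowest ratios, 6 had over 50% of their day 0 UMIs in 1 cell. These were SYT1, MS4A6A, PF4, IGJ, BCL3 and CLC, with folds of 120, 109, 47.5, 36.3, 30.8 and 25.3 as deposited. With capped counts the folds were 6.44, 21.1, 21.8, 22.6, 9.44 and 2.74. The other genes were found in 31 to 647 day 0 cells. S100A8 and S100A9, the calprotectin subunits of myeloid cells, were 171-fold lower [103, 303] and 42.2-fold lower in the day 2 library. The capped fold of S100A8 was 699 [236, 3421], as the cap set its 16 day 2 UMIs, in 3 cells, to 1 UMI per cell. Both genes were found in 37 day 0 cells, near the 31 cells of the monocyte-like cluster that they lead, so their ratios rest on few cells. AREG, the growth factor amphiregulin, stood at 209 CPM and 1.43 CPM, 147-fold lower [106, 210]. TSC22D3, a target of glucocorticoids, was 52.8-fold lower [46.0, 60.7] at 495 and 9.38 CPM. HIST2H2AA3, whose near-identical copy makes its count uncertain, was 55.6-fold lower. PPBP, a platelet chemokine, was 55.1-fold lower, or 87.4-fold with capped counts. PDE4B, a cyclic AMP phosphodiesterase, NFKBIZ, an NF-kappa-B regulator, and NR4A1 were 47.3-fold, 29.8-fold and 39.5-fold lower. Of the 15 highest genes 14, and of the 15 lowest 7, were also among the 15 with capped counts.

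**Figure D3:**
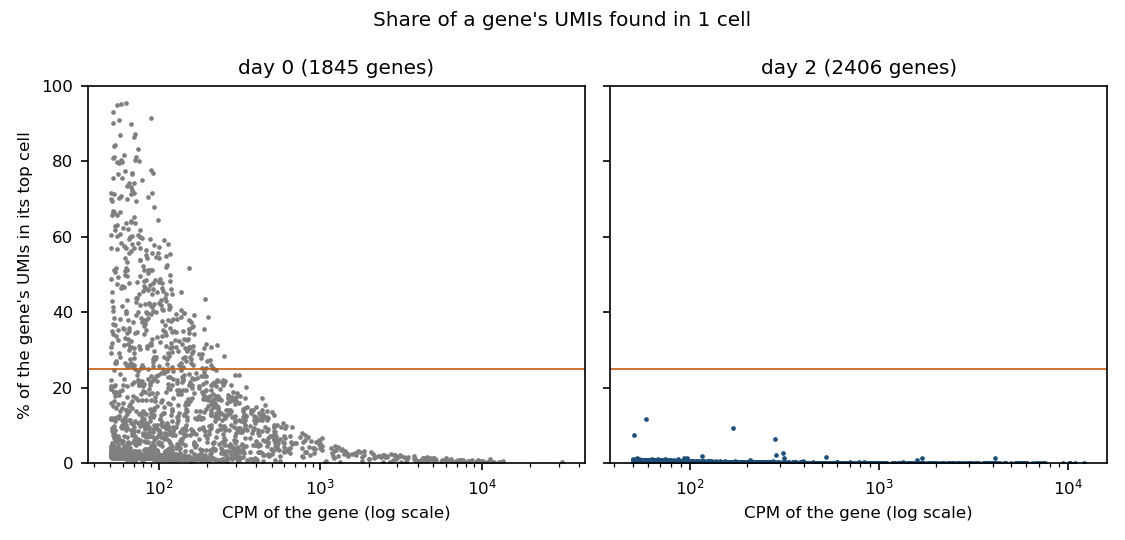
Percent of a gene's UMIs held by its top cell against the gene's CPM on a log scale, for genes at 50 CPM or more in the day 0 library (left) and the day 2 library (right), the line at 25%. Over all such genes, 371 of 1866 lay above 25% at day 0 and 0 of 2414 at day 2. The panels draw 1845 and 2406 genes.

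Markers of separate blood lineages differed in opposite directions. Of 19 erythroid markers, 15 were at least 2-fold higher in the day 2 library and 3 lower, with a median of 2.91 [1.79, 5.38] against 0.71. APOC1 and TFR2 were among the lower ones, at 3.93-fold and 3.57-fold, and without the 5% of cells with the most UMIs the log2 ratio of APOC1 turned to 0.65. Basophil, eosinophil and mast cell markers had a median of 1.81 [-0.47, 2.77] against 0.57, with 6 of 9 at least 2-fold higher and 1 lower. TPSAB1, a mast cell tryptase, was 9.86-fold higher [8.57, 11.4], or 16.4-fold with capped counts, and PRG2, the eosinophil major basic protein, 6.84-fold higher [5.01, 9.59], or 28.4-fold capped. TPSAB1 was not limited to the cluster of that lineage, and stood at 2176 CPM [2133, 2220] in the erythroid-like cluster against 1081 CPM [1050, 1111] in the basophil, eosinophil and mast cell-like one. Megakaryocyte and platelet markers were mixed, with 4 of 8 at least 2-fold higher, 2 lower and a median of 0.60 [-5.78, 4.19] against 0.50. CMTM5 was 18.2-fold higher [7.78, 56.2]. Granulocyte and monocyte progenitor markers had a median of -1.73 [-4.13, 0.93] against 0.68, with 8 of 13 lower and 2 higher. ELANE, neutrophil elastase, had 0 UMIs at day 2 and was at least 366-fold lower, or at least 30.1-fold capped, with 86 of its 103 day 0 UMIs in 1 cell, while CTSG, cathepsin G, was 5.64-fold higher [4.08, 8.04]. Monocyte and dendritic cell markers had a median of -5.40 [-7.41, 3.31] over 7 genes against 0.73, with 5 lower and 1 higher. The higher one was FCER1A, the IgE receptor chain also found on basophils and mast cells, at 9.92-fold [8.46, 11.7]. Its log2 ratio was -0.066 within the stem-like clusters. FCER1A likewise stood at 1621 CPM in the erythroid-like cluster and 515 CPM in the basophil, eosinophil and mast cell-like one. Plasmacytoid dendritic cell markers had a median of -1.84 [-5.18, 4.98] over 7 genes against 0.76. B lymphoid markers had a median of -2.74 [-7.50, -0.63] over 6 genes against 0.76, and T and natural killer cell markers -1.35 over 2 genes against 0.41. VPREB1, of the pre-B cell receptor, had 51 UMIs at day 0 and 1 UMI at day 2. The 13 markers of stem and primitive progenitor cells, 10 of them measured, had a median of -1.90 [-3.42, 0.57] against 0.54, with 8 lower and 1 higher, and 0 endothelial and stromal markers were measured.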

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

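The tests of globin in left-out barcodes were chosen after the result was seen. In the day 0 library, 2 of the 16 barcodes left out by the cell filter drew attention because globin genes, outside the main comparison's cells, made up 95.3% of their UMIs (1013 of 1063). These barcodes had 22 to 32 detected genes, while the 1512 kept day 0 cells together held 71 globin UMIs. With every barcode included, the globin level of the day 2 library was 17.3-fold that of the day 0 library, and with kept cells it was 263-fold. The ratios printed for HBG1, HBG2, HBA1 and HBA2 therefore rest on the filter of 200 detected genes.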

How the results depend on the processing

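The settings with capped counts and those that left out clusters were chosen after the data were seen. No paired analysis was possible because each group had 1 library and no label ties the libraries to a donor. Over 37 list medians and the 14 settings fixed beforehand, 468 of 518 values stayed inside the main interval over genes, 46 moved outside it with the same sign or from an interval that included 0, and 4 changed sign. In the 4 later settings 139 of 148 stayed and 9 moved. Over 126 named genes, 1014 of 1512 values in settings fixed beforehand and 345 of 480 in later ones stayed inside the counting interval, 492 and 132 moved, and 6 and 3 changed sign. A change of sign was counted only for lists whose interval excluded 0 and for genes at least 2-fold apart whose interval excluded 1. Among the other values, 18 and 6 of lists and 28 and 4 of genes, such as PDHB with capped counts, also crossed 0. The summed stem-like cells of uncapped counts gave no value, since no day 0 cluster of the main clustering had that name, and the setting without doublets could not differ, since 0 were called. In the capped stem-like cells some genes, such as HBA1, lay under the floor and have no value.

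Scaling sets how far the libraries lie apart. The median log2 ratio of all measured genes was 0.59 as CPM, 0.32 with TMM, 0.16 with median-of-ratios, 0.28 per UMI outside ribosomal protein and mitochondrially encoded genes and 2.30 per cell without scaling. Per cell without scaling, the medians that changed sign from an interval that excluded 0 were 0.62 for stem, 0.96 for class I, 1.00 for class II and 1.19 for cytosolic ribosomal protein genes, and the genes were CD34 at 0.66, SPINK2 at 0.33, GADD45A at 0.17, DDIT4 at 0.15 and HLA-DRA at 0.51. All of these lie below the shift of all genes. In that setting p53 targets were at 2.27, mitochondrially encoded genes at 2.08, the nuclear respiratory chain at 2.47, glycolysis at 2.78, S phase at 3.55, G2 and M phase at 5.14, immediate early genes at 0.59 (from -1.12 with an interval that included 0) and mitochondrial ribosomal proteins at 3.02. The nuclear respiratory chain was at 0.50 with TMM, 0.33 with median-of-ratios, 0.45 outside ribosomal protein and mitochondrially encoded genes, 0.68 with 500 detected genes and 0.93 with capped counts, and mitochondrial ribosomal proteins at 1.04, 0.88 and 1.00 under the first 3 of these. Counts of genes at least 2-fold higher depended on scaling as well. From CPM to TMM to median-of-ratios they went from 20 to 12 to 9 for the nuclear respiratory chain, 41 to 26 to 22 for mitochondrial ribosomal proteins, 11 to 8 to 5 for glycolysis, 11 to 8 to 4 for the tricarboxylic acid cycle, 7 to 2 to 1 for fusion and fission, 11 to 9 to 5 for chaperones and 13 to 8 to 6 for ribosome biogenesis. With capped counts the nuclear respiratory chain instead had 34 such genes, and 44 in the stem-like clusters. Genes at least 2-fold lower went from 5 to 17 to 33 for cytosolic ribosomal proteins, 2 to 5 to 6 for class I and 1 to 3 to 3 for class II.

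A pseudocount of 10 CPM gave 1.68 for G2 and M phase genes. In stem-like cells with capped counts, G2 and M phase genes were at 2.47, immediate early genes at -2.47, the nuclear respiratory chain at 1.10 and mitochondrial ribosomal proteins at 1.56, while CD34 at 0.12, GATA2 at -0.91 and FCER1A at -0.066 changed sign. APOC1 was at 0.65 without the 5% of cells with the most UMIs. The cause was not tested for any of these. Thinned to 2000 UMIs in place of 1000, the day 0 share of cells with AVP went from 24.8% to 14.8% and that with TOP2A from 0.568% to 3.55%, with 366 day 0 cells in place of 1232, while the day 2 shares went from 4.25% to 7.63% and from 15.2% to 28.5%.

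Cluster shares depended on the clustering. Day 2 erythroid-like cells, 11.5% in the main clustering, were 13.6% and 7.40% at resolutions 0.4 and 1.2, 7.5% without cycle genes, 7.28% after thinning and 12.5% with capped counts. Day 2 stem-like cells, 12.9%, were 46.5%, 11.9%, 43.9% without cycle genes and 15.5% capped, and after thinning no day 2 cluster had that name. Granulocyte and monocyte progenitor-like cells, 4.96%, were 20.7%, 5.94%, 16.0%, 15.3% and 13.9% in the order of the erythroid-like values. Basophil, eosinophil and mast cell-like cells, 16.1%, were 13.3% at resolution 1.2, 11.1% after thinning and 8.93% capped, and no cluster had that name at resolution 0.4. Day 0 monocyte-like cells, 2.05%, were 0.812% after thinning. Other day 0 names came and went with the clustering. These were stem-like at 67.1% (resolution 0.4) and 21.0% (capped), basophil, eosinophil and mast cell-like at 2.71% (resolution 1.2), and erythroid-like at 21.2% and plasmacytoid dendritic cell-like at 18.3% (capped). Depth limits the day 0 library most, where 1 UMI is worth 0.40 CPM and genes under 3 UMIs were ranked at a floor of 3.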

Other observations

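Among the tests in this part, those of globin in the day 2 cells without a globin UMI and in single clusters, and the genes of the first paragraph, were chosen after the results were seen. Those of the aryl hydrocarbon receptor and of serine metabolism come from no fixed list, so they say nothing of a pathway as a whole. Beside CYP1B1 and CYP1A1, a pair of other genes known as targets of the aryl hydrocarbon receptor, a ligand-activated transcription factor, were higher in the day 2 library. AHRR, the repressor of that receptor, had 0 UMIs at day 0 and was at least 10.4-fold higher at day 2, and TIPARP was 5.25-fold higher [2.92, 10.6]. CYP1B1 was present in each of the 8 day 2 clusters, at 317 to 675 CPM. Of 4 genes of serine and one-carbon metabolism beside PSAT1, 3 were at least 2-fold higher, with MTHFD2 at 5.08-fold [4.17, 6.25], PHGDH at 4.27-fold [3.49, 5.28] and SHMT2 at 2.65-fold [2.23, 3.16], while PSPH stood at 1.34-fold with an interval that included 1 [0.929, 1.99]. Of the immediate early list, with 13 of 25 genes at least 2-fold lower and 6 higher, NFKBIA was 12.3-fold lower, DUSP1 10.5-fold lower, FOS 5.12-fold lower and JUN 4.63-fold lower in the day 2 library.

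Within the day 2 library, G2 and M phase genes summed to 1958 CPM [1898, 2019] in the stem-like cluster of 633 cells. Their sums were 4252 to 9839 CPM in the other 7 clusters, of which 1 was led by such genes. That KIF20A-led cluster held AVP at 93.1 CPM and CD34 at 164 CPM. The clustering used cycle genes, and without them 43.9% of day 2 cells were stem-like, against 12.9%. These sums therefore cannot tell whether stem-like cells cycled less. Class II genes summed to 3441 CPM [3362, 3521] in the stem-like cluster and to 981 to 2643 CPM in the others. CDKN1A did not set the stem-like cluster apart. It stood at 13.9 CPM [9.30, 19.9] there, at 10.2 to 16.5 CPM in the granulocyte and monocyte progenitor-like, MZB1-led and KIF20A-led clusters and at 34.2 to 80.6 CPM in the others.

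Single day 0 cells held many UMIs of 1 gene that other cells held at under 2 UMIs on average. There were 1605 such entries of 20 UMIs or more in 907 cells and 1178 genes at day 0, with a median of 55 UMIs, and 392 at day 2. At least 2 such entries were held by 422 cells, against 427 by chance placing, a ratio of 0.988. This cannot decide on rare cell types. The bound set for them, 3 times the chance number, was out of reach with 1605 entries. Entries gathered in few cells also need not raise that number. As the entries lay in 60.0% of day 0 cells, they were not confined to few cells, but rare cells among these are not excluded. Per 1000 pairs of a detected gene and a cell there were 1.88 [1.5, 2.32], 2.06 [1.84, 2.30] and 2.80 [2.64, 2.96] entries, from genes found in the fewest to those found in the most cells. This 1.49-fold range exceeds counting error but lies under the 3-fold bound set for a like chance per detected molecule, so few molecules counted as many UMIs may be the source. What step did so was not tested, and folds of genes such as HLF and SYT1 are best read from capped counts.

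Nuclear respiratory chain, mitochondrial ribosomal protein and glycolysis genes had medians above the 0.59 of all measured genes, which the glycolysis interval included. Their medians lay at percentile 99.99 of matched random lists for the nuclear respiratory chain, 100 for mitochondrial ribosomal proteins and 99.75 for glycolysis, and at 100, 100 and 99.15 with capped counts. For mitochondrial ribosomal proteins, with a random median of 0.55, this argues against a shift shared by genes of like abundance. The random medians of the respiratory chain and glycolysis, 0.31 and 0.45, were lower. Their random lists could hold cytosolic ribosomal protein genes, which were lower at day 2, so the percentiles alone cannot decide there. Fewer ribosomal protein UMIs at day 2 did not account for all of the respiratory chain difference, whose median was 0.76 [0.69, 0.85] as CPM and 0.45 [0.38, 0.55] on UMIs outside ribosomal protein and mitochondrially encoded genes. The median of all measured genes was 0.59 and 0.28 in these scalings. Some mitochondrial lists lay inside their random lists, at percentile 63.2 for mitochondrially encoded genes, 70.9 for fusion, fission and mitophagy and 91.4 for biogenesis. These lists held 10 to 17 measured genes and had wide random ranges, such as -0.48 to 1.42 for biogenesis. The biogenesis median of 1.18 exceeded that of the nuclear respiratory chain, so the percentiles do not show that these lists differed from it. Culture with cytokines and valproic acid remains open as a biological explanation and could not be separated from time, sort or donor.

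Globin UMIs were found in all 8 day 2 clusters, at 41469 CPM in the erythroid-like cluster, which globins helped to define, 9983 CPM in the IGFBP5-led cluster of 164 cells and 69.4 to 226 CPM in the other 6. Of the 4918 day 2 cells, 53.9% [52.5, 55.3] held 0 globin UMIs, where a common share of each cell's UMIs would leave under 1%. This argues only against free RNA at a like level in every cell as the whole source. The erythroid-like cluster held 183250 of the 198883 globin UMIs behind that share. The comparison therefore cannot decide on a low level of free RNA in the other clusters. The ratio of alpha-globin to gamma-globin UMIs was 1.85 times as high outside the erythroid-like cluster as inside it [1.77, 1.93], but the IGFBP5-led cluster, with 12901 globin UMIs, sets much of that value. By cluster, the ratio relative to the erythroid-like cluster was 6.42 [5.54, 7.44] in the PRSS23-led, 4.14 [3.25, 5.24] in the basophil, eosinophil and mast cell-like, 2.45 [1.89, 3.14] in the MZB1-led and 1.60 [1.52, 1.68] in the IGFBP5-led cluster. These values argue against free RNA from erythroid-like cells as the only source there, with the least margin in the IGFBP5-led cluster. In the stem-like, KIF20A-led and granulocyte and monocyte progenitor-like clusters, at 1.34 [0.764, 2.23], 1.10 [0.527, 2.09] and 2.26 [1.11, 4.30], free RNA and low expression cannot be told apart with so few UMIs. Differentiation in culture stays open and was not tested.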
